A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

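The study sequenced polyadenylated RNA from 10 yeast cultures, 2 separate fermentations for each of 5 strains of the S288C background: LAB (its genotype is given as wild type), WY7, WY15, WY23 and the med15 deletion. Per the labels, cultures grew in 5 mL of supplemented white grape juice and were collected at a weight loss of 35%, after about 37 h (48 h for the deletion). RNA was taken out with hot acid phenol, stranded messenger RNA libraries were made from 150 to 200 ng with 13 cycles of PCR, and all were pooled for paired reads of 150 bp on 1 lane. No batch is given in the labels.

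The submitters' processing notes name Trim Galore, Bowtie2, featureCounts and DESeq2 and the genome builds sacCer3 and R64; versions and settings are not given in the sources used here, nor is whether the counting used the strand. The values deposited by the authors are a table of signal per gene and library, namely read counts divided by 1 DESeq2 size factor per library. Every value of a library was found to be a whole multiple of 1 step (100% of values within 1e-06), so the read counts were recovered and used for depth, for edgeR and DESeq2, and for counting limits. The largest deviation of a recovered count from a whole number is 1.5e-09. Recovered totals are 22.7 to 29.3 M reads per library. In WY15 replicate 2 the step is close to 1, so that low values also look whole without division. All 10 columns were used.

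The table has 6600 genes. Names and positions came from the R64 reference annotation: 5917 identifiers matched and 683 did not, these with a median level of 11.5 normalized counts, and they were tested without a name and took 0.326 to 0.455% of the reads of a library. The 28 mitochondrial genes are listed at 0 in every library, so the list of mitochondrial genes could not be tested, and 119 genes have no read. Genes whose sequence, introns included, matches another at 97% or more over at least 150 bp were marked as near-identical with BLAST+ 2.17.0. That mark also takes in some overlapping neighbours. Genes that overlap another were marked apart. Reads of either kind may be assigned to the wrong gene.

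The comparisons used limma 3.58.1 in R 4.3.3 on log2(value + 1), genes with a mean of at least 10 (6065), 1 fit with 5 group means, 5 residual degrees of freedom and a prior of 3.05, a variance trend without robust weights, two-sided tests and a Benjamini-Hochberg adjusted p under 0.05 in each comparison. 10 comparisons were made: the deletion against LAB and against the mean of the 4 *MED15* strains, each WY allele and their mean against LAB, the 3 pairs of WY alleles, and any difference among the 4 alleles. The 37 gene lists, from textbook knowledge, cover carbon metabolism and transport, amino acid synthesis and uptake, nitrogen, vitamins, stress, respiration, cell surface, ribosomes, Mediator, mating, meiosis and selection markers. 36 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Of the list genes only *FLO8* had no matched identifier.

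The named genes follow a rule set before the data were examined. *MED15* comes first. Then come genes with a standard name, a mean of at least 50, an adjusted p under 0.05 and no overlap between the libraries compared, ranked by absolute log2 change: 12 higher and 12 lower for the deletion against LAB, 10 and 10 for the mean of the WY alleles and 5 and 5 for each WY allele, where none passed. For each list described, up to 4 called genes with the largest change and up to 2 abundant genes that did not pass were open to naming, and *ADH1*, *ADH2*, *PDC1* and *GAP1* are given whatever their values. For a gene with 0 reads a floor of 3 reads per library was used.

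The test was tried on simulated data with the replicate spread of these libraries and 200 changed genes. It called 98.5% of 4-fold, 88.5% of 2-fold and 7% of 1.5-fold changes for the deletion against LAB, and 99.5%, 86.5% and 7% for WY7 against LAB. For the mean of the WY alleles it called 100%, 91.5% and 52%. Wrongly called genes numbered 1 to 13 per run. Changed genes were drawn only from those with a mean of at least 50, and genes varied independently of each other. These figures may therefore be too favourable for weaker genes and for replicates whose genes move together. The list test was tried apart, on simulated independent genes that all had the same spread. Of 36 lists, the 4 shifted by a log2 of 0.5 were called and 0 others. Genes of a list can move together between replicates in these libraries, so that run does not measure false list calls here. Reads alone give little of the error: within-strain differences exceeded counting error with a chi-square per degree of freedom of 21.7 (WY23) to 181 (WY15). The replicate numbers of different strains were checked for pairing and show none common to all strains. Of 10 correlations of within-strain differences 3 exceed 0.1, and they range from -0.50 to 0.41. Those 3 lie among WY7, WY23 and the deletion (0.26 to 0.41), so shared handling of some replicates is not excluded.

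Alternatives, with effects given in the closing section, were pseudocounts of 0.5 and 8, no filter and a mean of at least 50, TMM factors, quantile normalization and equal sums, robust weights, a replicate block, only the groups compared, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, each library left out in turn, an estimated correlation and fry for the lists, and no shared library for the overlap of effects. After seeing the data, 2 pairs of libraries were also left out together (LAB replicate 1 with WY15 replicate 2, and LAB replicate 2 with WY7 replicate 1), the list tests between WY alleles were added, and the marker list was tested without *URA3*. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the comparisons themselves.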

Results

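Messenger RNA was sequenced from 5 yeast strains of the S288C background fermenting supplemented white grape juice in 5 mL cultures, with 2 libraries per strain from separate fermentations. 4 strains carry a *MED15* allele (LAB, WY7, WY15 and WY23) and the other lacks *MED15*, which encodes a tail subunit of Mediator, the complex that links DNA-bound activators to RNA polymerase II. All were harvested at a weight loss of 35%, after about 37 h for the *MED15* strains and 48 h for the deletion. The libraries hold 22669536 to 29320432 gene-assigned reads each (22.7 to 29.3 M), spread over 6600 listed genes, of which 6065 had a mean of at least 10 normalized counts and were tested. All values below are normalized counts, or log2 changes of them with the standard error (SE) of the fit, from 2 libraries per strain. The series title points to ethanol and amino acid metabolism as the question, so genes of these pathways were grouped into lists fixed before the data were examined, as were the tests, the named-gene rule and most alternatives.

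*MED15* itself (chromosome XV, 234940 to 238185, R64 coordinates) had 8238 and 8844 normalized counts in the LAB libraries, 9497 and 8837 in WY7, 8521 and 8797 in WY15, 10571 and 10958 in WY23, and 12.1 and 11.9 in the deletion. These rest on 6926 to 10081 reads per library in the *MED15* strains and on 15 reads in each deletion library. The deletion mean is 709-fold below the LAB mean (log2 change -9.35, SE 0.08, adjusted p = 1.8e-10). Among the alleles, WY23 stood highest, with a log2 difference to LAB of 0.33 (SE 0.08, adjusted p = 0.53 by limma). DESeq2 on the recovered reads calls that difference (adjusted p = 0.023).

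Another gene separates the deletion libraries completely. *URA3*, which encodes a pyrimidine synthesis enzyme and is a common selection marker, had 0 reads in the 8 *MED15* libraries (210.8 M reads together) and 3971 and 4037 reads in the deletion libraries, at least 839-fold higher when the lower deletion value is set against the highest floor of 3 reads in the other 8. That bound covers counting error only. *LEU2* and *LYS2*, also common markers, are at 0 reads in all 10 libraries. The labels do not mention *URA3*, and every comparison with the deletion carries this difference as well as the later harvest.

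The largest axis of variation parted the deletion from the other strains: the first principal component held 70.0% of the variance, and no later one held more than 9.41%. Within strains, the WY23 pair was closest (median absolute log2 difference 0.08, 48 genes more than 2-fold apart) and the WY15 pair widest (0.20, 187 genes), with LAB at 0.18 and 157 genes. In the LAB and WY15 pairs the low-oxygen genes differed most. *DAN1*, which encodes a cell wall protein made under low oxygen, had 423 and 3020 normalized counts in LAB replicates 1 and 2, and 6054 and 233 in WY15 replicates 1 and 2. *OLE1*, the fatty acid desaturase, had 77775 and 203609 in LAB and 165545 and 49685 in WY15. Both genes were picked out after their values were seen. As a list, the low-oxygen genes were lower in LAB replicate 1 than in replicate 2 by a median log2 of -1.05, and lower in WY15 replicate 2 than in replicate 1 by -1.41.

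In the deletion against LAB, 13 of 17 glycolysis genes and 17 of 25 nitrogen catabolite repressed genes fell, as did single abundant genes of sugar uptake and of the ethanol pathway, while 14 of 20 meiosis genes and 22 of 33 respiratory chain genes rose. Of 19 amino acid permeases 7 rose and 5 fell. Under quantile normalization 6 glycolysis genes are called lower and 1 higher. Camera calls 4 of these lists with the preset correlation and none with an estimated one (adjusted p = 0.40 to 0.66 with an estimated correlation for the 4). Permeases are not called by camera, and fry, which uses no preset correlation, keeps the 4. *HXT3*, a hexose transporter and one of the most abundant messages in LAB, fell from 199984 (SD 21260) to 22960 (SD 1092), a log2 change of -3.12 (SE 0.21, adjusted p = 6.4e-05). The main fermentative alcohol dehydrogenase gene *ADH1* fell by 1.92 (SE 0.24, adjusted p = 0.0008) and *PDC1*, the main pyruvate decarboxylase, by 1.24 (SE 0.15, adjusted p = 0.0006). Under quantile normalization these changes are -0.78 and -0.50, both still called. *ALD6*, which makes acetate from acetaldehyde, fell by 4.25 (SE 0.79, adjusted p = 0.0042), with 4917 and 1022 normalized counts in the deletion libraries. The log2 change is -3.11 (adjusted p = 0.023) without deletion replicate 2 and -5.38 (0.0036) without replicate 1. In the other direction, the glutamine permease gene *GNP1* rose from 672 (SD 178) to 8364 (SD 1660), a log2 change of 3.65 (SE 0.38), and the methionine permease gene *MUP1* from 862 (SD 422) to 9984 (SD 3097), a log2 change of 3.59 (SE 0.42).

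By limma, 2219 genes changed between the deletion and LAB, 1147 higher and 1072 lower, and of these 415 rose and 317 fell by at least 2-fold. edgeR calls 2241 genes and DESeq2 calls 2520, and without LAB replicate 2 and WY7 replicate 1, left out together after seeing the data, limma calls 1413. The share of genes that fell was highest among abundant messages: of the 100 most abundant genes 82 fell, 0 rose and the median log2 change was -1.23. Of the 2000 genes that follow the 2000 most abundant, 330 fell and 282 rose, and among the 2065 genes below the 4000 most abundant, 698 rose and 174 fell. The 100 most abundant genes took 24.6 to 28.2% of the reads in the *MED15* libraries and 12.7 and 12.8% in the deletion. Abundance was ranked by the mean over all 10 libraries, 8 of them with *MED15*. Genes that fall in the deletion are thereby ranked higher, so part of this pattern is built in. The deposited values sum to 25.9 to 29.5 M in the *MED15* libraries and to 20.8 and 20.9 M in the deletion, so the split depends on the scaling: with each library scaled to the same sum, 87.1% of 3296 called genes are higher, against 51.7% on the deposited scale. That scaling moves the median of all genes by 0.36, and the directions given here are relative to the deposited scale unless a sentence says otherwise.

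Besides *URA3*, *GNP1* and *MUP1*, the genes that rose most under the named-gene rule are *CDA2*, a chitin deacetylase gene of the spore wall (16.2, SD 0.31, to 548, SD 108; log2 change 4.98), its neighbour *DPA10* (4.81), the sodium pump gene *ENA1* (4.48; it has near-identical copies, so its level is uncertain), *CSS1* (3.86), *HXT14* (3.83), *SPO75*, a sporulation gene (3.72), *AMF1* (3.56), *HFM1*, a meiotic DNA helicase gene (3.46), and *OPT2*, an oligopeptide transporter gene (3.29). Besides *MED15*, *ALD6* and *HXT3*, the largest called falls under that rule are *HXT4* (47435, SD 22134, to 2179, SD 1968; log2 change -4.74, SE 0.63), the water channel gene *AQY1* (-4.47), the kinase gene *RCK1* (-4.27), the hexokinase gene *HXK1* (-4.10), the alpha-factor gene *MF(ALPHA)1* (-3.62), *TMA10* (-3.57), *ICY1* (-3.56), *BAG7* (-3.26) and *HXT6* (-3.20; a near-identical copy makes its level uncertain). The adjusted p-values, *MED15* aside, lie between 9e-06 and 0.0042. Some sizes rest on single libraries. Without deletion replicate 2 the changes are -3.65 for *HXT4*, -3.46 for *AQY1*, -3.50 for *RCK1*, -2.87 for *TMA10* and -2.44 for *BAG7*. Without LAB replicate 2 that of *HXT6* is -2.22, and without LAB replicate 1 those of *ENA1* and *SPO75* are 3.57 and 3.04. All stay called. *HXT2*, also among these falls, is at -4.72 with an SE of 1.59 and an adjusted p of 0.049. Its call is lost with edgeR (adjusted p = 0.13), with DESeq2 (0.092) and without any 1 of 9 libraries, the highest being 0.20 without deletion replicate 2, where its log2 change is -1.88.

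**Figure D1:**
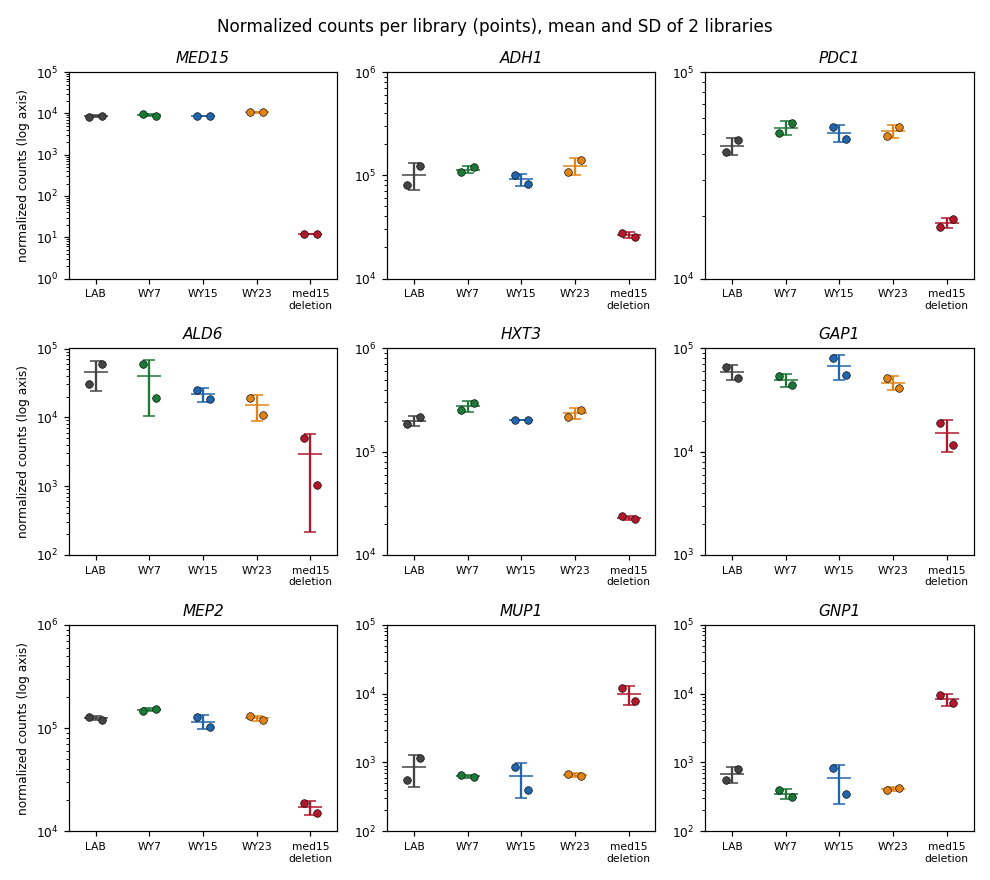
Normalized counts (log axis, each panel with its own range) of 9 genes in the 2 libraries of each strain; points are libraries and bars are the mean with SD. *MED15* is near 12 in both deletion libraries, *ADH1*, *PDC1*, *ALD6*, *HXT3*, *GAP1* and *MEP2* are lower there than in all 8 other libraries, and *MUP1* and *GNP1* are higher.

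Of 17 glycolysis genes tested, 13 fell, 0 rose and 4 did not pass (14 fell adjusted over the list alone), with a median log2 change of -1.05. Under quantile normalization 6 are lower and 1 higher, with a median of -0.40, and under equal sums 9 are lower and 0 higher (-0.69). Examples are *HXK1* (-4.10), the pyruvate kinase gene *CDC19* (-1.97) and the enolase gene *ENO1* (-1.84), the last 2 at -0.67 and -0.61 under quantile normalization and still called, while the abundant *ENO2* is at -0.71 (adjusted p = 0.12, but 0.024 and 0.025 without WY15 replicate 1 or 2). Among 18 ethanol and acetate enzymes 8 fell, 3 rose and 7 did not pass (8 and 4 adjusted over the list alone), with *ALD4* at -2.12 beside *ALD6*, *ADH1* and *PDC1*. *ADH2*, whose enzyme turns ethanol back into acetaldehyde, is at -1.11 (SE 0.76, adjusted p = 0.28), with 498 and 1213 normalized counts in LAB and 833 and 154 in the deletion. Without deletion replicate 1 it is called (-2.32, adjusted p = 0.033). Of 11 glycerol genes 6 fell and 0 rose, over all genes and adjusted over the list alone, led by *GPD1*, the glycerol phosphate dehydrogenase gene (-2.65, SE 0.23), and *GUT1* (-1.78). Of 16 trehalose and glycogen genes 6 fell and 0 rose (7 and 1 adjusted over the list alone), among them *GSY2*, a glycogen synthase gene (-2.23), and *UGP1* (-2.06). The 16 hexose transporters went both ways, 7 lower and 3 higher, over all genes and adjusted over the list alone. Under quantile normalization 5 glycerol genes are lower and 1 higher, 6 trehalose and glycogen genes lower and 3 higher, and 8 hexose transporters lower and 2 higher.

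Of 25 nitrogen catabolite repressed genes, which serve poor nitrogen sources, 17 fell and 4 rose, over all genes and adjusted over the list alone (median -1.64). The allantoin genes *DAL7* (-3.02) and *DAL3* (-2.81) and the ammonium permease gene *MEP2* (-2.88, SE 0.19) fell, as did *GAP1*, the general amino acid permease gene (-1.99, SE 0.29, adjusted p = 0.0014), while *OPT2* rose. In the sulfate and methionine list 16 of 26 genes fell and only *MUP1* rose (18 and 1 adjusted over the list alone), with *MET3*, which encodes the first enzyme of sulfate assimilation, at -1.84 and the activator gene *MET32* at -1.66. Arginine synthesis had 6 of 10 genes lower and 0 higher, over all genes and adjusted over the list alone, with *ARG3* at -1.73 and *ARG56* at -1.14. Under quantile normalization 2 are lower and 1 higher, and the list median of -0.97 becomes -0.04, though *ARG3* (-1.77) and *ARG56* (-0.84) stay called. Branched-chain amino acid synthesis had 7 of 11 lower and 0 higher by both counts, with *LEU4* at -1.37 and *ILV2* at -1.31; the list median of -0.82 turns to 0.29 under quantile normalization, where 5 are higher and 1 lower and *LEU4* (-0.08) and *ILV2* (-0.11) are no longer called. Of 19 amino acid permeases 7 rose and 5 fell by both counts, with *TAT1* at 3.03 (it overlaps another gene, so its count is uncertain) and the proline permease gene *PUT4* at -2.19. Under quantile normalization 17 nitrogen catabolite repressed genes are lower and 4 higher, 12 sulfate and methionine genes lower and 3 higher, and 10 permeases higher and 4 lower.

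Of 9 lysine genes 2 fell and 1 rose, of 7 histidine genes 2 fell and 0 rose, and of 12 aromatic genes 2 fell and 2 rose, with the same counts adjusted over each list alone; *LYS20*, the first enzyme of lysine synthesis, is the clearest (-1.98, SE 0.16), as is *HIS4* (-1.55) for histidine. The medians of these 3 lists (-0.14, -0.16 and -0.01) turn positive under quantile normalization and under equal sums; of the aromatic genes 5 are then higher and 1 lower, and 6 and 1. In the list of glutamate, proline, serine and glycine genes 7 of 22 rose and 6 fell (9 and 7 adjusted over the list alone). This balance depends on the scaling. The counts are 12 higher and 2 lower under quantile normalization (median 0.46, against 0.10) and 13 and 2 under equal sums. Members include *GLN1*, the glutamine synthetase gene, at -1.39, a call lost under quantile normalization, and *GDH3* at 1.29.

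Among 33 nuclear genes of the respiratory chain 22 rose and 1 fell (24 and 1 adjusted over the list alone, median 0.50), with *CYC1*, the cytochrome c gene, at 2.40 and *ATP16* at 0.88, while *COX5B*, a low-oxygen subunit, is at -1.17. Of 17 fatty acid beta-oxidation genes 8 rose and 0 fell by both counts, led by *POT1* (2.95, SE 0.17) and *SPS19* (2.22). Of 20 meiosis and sporulation genes 14 rose and 1 fell (14 and 2 adjusted over the list alone), with *SPS2* at 3.06, *HOP1* at 2.99 and *SPR3* at 2.60. All 5 flocculin genes are higher, 4 of them called (5 adjusted over the list alone), with *FLO11*, an adhesin gene, at 1.54. Of 16 seripauperin genes 11 rose and 1 fell by both counts, though most are near-identical copies, so the level of any 1 of them is uncertain. The thiamine and vitamin B6 list split: 11 of 20 rose and 4 fell (12 and 4 adjusted over the list alone), with *THI5* at 1.85 and *SNZ2* at 2.49, both with near-identical copies, and *THI4* at -2.13. General stress genes fell, 11 of 18 with 1 higher (12 and 2 adjusted over the list alone), among them *TMA10*, *SPI1* (-2.03) and *HOR7* (-1.91). Under quantile normalization 5 are lower and 3 higher, the list median goes from -0.98 to -0.38, and *SPI1* (-1.09) and *HOR7* (-1.02) stay called. That scale gives 29 respiratory chain genes higher and 1 lower, 13 meiosis genes higher and 2 lower, and 3 flocculin genes higher. It also gives 6 seripauperin genes higher and 2 lower, 13 thiamine and vitamin B6 genes higher and 2 lower, and the same counts for beta-oxidation.

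The list test, camera with a preset correlation of 0.01, calls 15 of 36 lists between the deletion and LAB, 7 higher and 8 lower. The adjusted p-values of the lower ones are 1.1e-05 for glycolysis and for the nitrogen catabolite repressed genes, 2.3e-05 for sulfate and methionine, 0.0053 for general stress, 0.012 for branched-chain synthesis, 0.017 for arginine, 0.022 for glycerol and 0.026 for trehalose and glycogen. Those of the higher ones are 2.3e-05 for meiosis, 2.4e-05 for the respiratory chain, 0.0045 for seripauperins, 0.0052 for flocculins, 0.012 for thiamine, 0.027 for ribosomal proteins (6 of 139 genes higher, 1 adjusted over the list alone, median 0.19, but 20 under quantile normalization, median 0.37, and 61 under equal sums, median 0.55) and 0.031 for beta-oxidation. With a correlation estimated from the residuals all 15 calls are lost: the adjusted p = 0.40 with an estimated correlation for glycerol, seripauperins, flocculins and meiosis, 0.63 for glycolysis and sulfate, 0.88 for ribosomal proteins and 0.66 to 0.70 for the other 8. That estimate rests on 5 residual degrees of freedom, and the power of the test with it was not measured. Losing every call therefore does not show that the lists stayed unchanged. Ethanol and acetate enzymes (adjusted p = 0.057) and hexose transporters (0.091) missed the threshold. Camera compares a list with all other tested genes, whatever their abundance. The glycolysis median of -1.05 stands beside -1.23 for the 100 most abundant genes, of which 82 fell. No list was tested against genes of like abundance, so the list calls do not separate a pathway from the abundance trend. fry, which asks whether a list moves on balance without comparing it with other genes, calls 21 lists. It loses trehalose and glycogen (0.063) and ribosomal proteins (0.63), keeps the other 13, and gains 8, among them ethanol and acetate enzymes (0.0086) and hexose transporters (0.030). Single libraries decide some calls: arginine is lost without LAB replicate 1 (0.068), ribosomal proteins without LAB replicate 1 (0.92) or deletion replicate 2 (0.23), and beta-oxidation without deletion replicate 1 (0.066). Without LAB replicate 1 and WY15 replicate 2 together, the pair low in low-oxygen genes and left out only after seeing the data, arginine (0.094), branched-chain synthesis (0.059) and ribosomal proteins (0.86) are lost. Hexose transporters pass without LAB replicate 1 (0.027) or deletion replicate 1 (0.019), and ethanol and acetate enzymes pass without any 1 of 5 libraries (0.019 to 0.050).

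**Figure D2:**
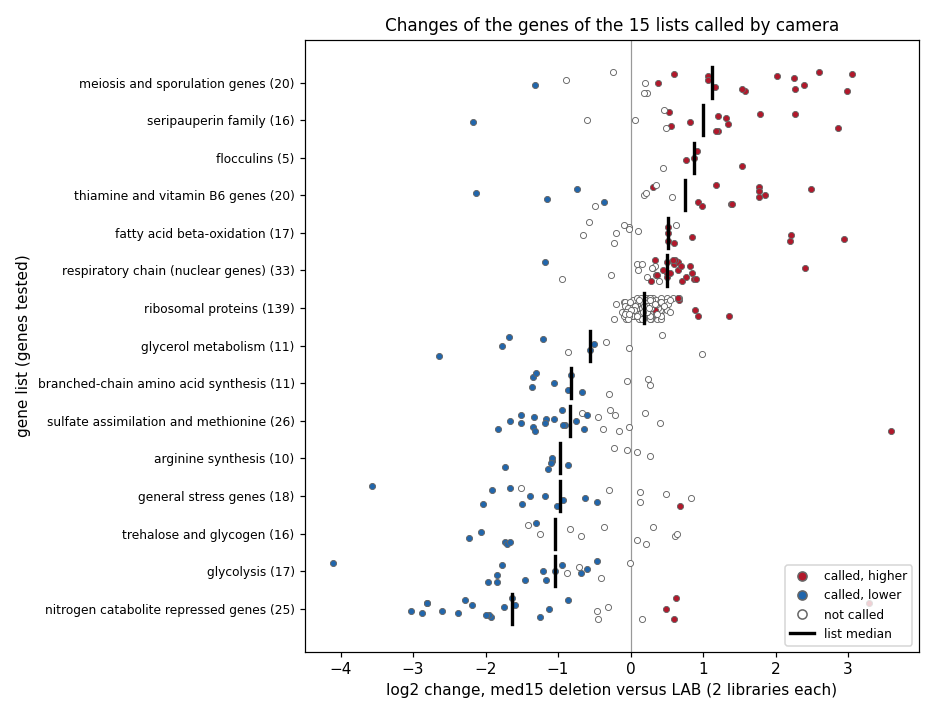
Log2 change of each tested gene, deletion versus LAB (horizontal axis), for the 15 lists called by camera with a preset correlation (vertical axis, genes tested in brackets). Red and blue points are genes called higher and lower by limma, and open points are not called. Black bars are list medians, from -1.64 (nitrogen catabolite repressed genes) to 1.12 (meiosis and sporulation genes). Under quantile normalization the median of branched-chain amino acid synthesis turns positive and that of arginine synthesis is -0.04.

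The deletion was also set against the mean of the 4 *MED15* strains, so that the result rests less on the 2 LAB libraries. The number of genes rose to 3027 (1554 higher, 1473 lower; edgeR 3034, DESeq2 3201), and with libraries scaled to equal sums 4171 are called, 88.1% of them higher. 2186 genes are called in both comparisons, all in the same direction, 33 only against LAB and 841 only against the mean. Both comparisons use the same deletion libraries, and the mean includes LAB, so agreement between them is largely built in. 15 lists are called, 14 of them shared and in the same direction as against LAB, with iron uptake in place of ribosomal proteins. None of the 15 is called with an estimated correlation, where the lowest adjusted p = 0.52 with an estimated correlation.

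Between the wine-strain alleles and LAB, differences were small and no single gene passed by limma or edgeR. The mean of the 3 WY alleles lies slightly above LAB for arginine synthesis, where 10 of 10 genes are higher (median log2 0.34) though none passed. The abundant *ARG4* is at 0.44 (SE 0.16) and *CPA1*, whose enzyme makes carbamoyl phosphate for arginine, at 0.40 (SE 0.15), both with an adjusted p of 0.83. Histidine (7 of 7 genes, median 0.31), lysine (9 of 9, 0.17), branched-chain (10 of 11, 0.20) and aromatic amino acid synthesis (10 of 12, 0.18) lie on the same side. So do heat shock chaperones (22 of 22, 0.31), ribosomal proteins (138 of 139, 0.17), glycolysis (14 of 17, 0.21), thiamine genes (15 of 20, 0.13) and the glutamate, proline, serine and glycine list (15 of 22, 0.06). The median of the last turns negative under equal sums, where those of thiamine genes and ribosomal proteins are 0.06 and 0.10. Under quantile normalization the glycolysis and branched-chain medians are 0.07 and 0.08. Fatty acid beta-oxidation (0 of 17 genes above LAB, median -0.15), hexose transporters (4 of 16, -0.33), iron uptake (1 of 18, -0.22), the tricarboxylic acid cycle (2 of 18, -0.09) and meiosis (6 of 20, -0.11) lie on the other side. The ethanol genes and *GAP1* gave no call: *ADH1* is at 0.12 (SE 0.20), *PDC1* at 0.25 (SE 0.12), *ADH2* at -0.49 (SE 0.62) and *GAP1* at -0.14 (SE 0.24), with adjusted p-values of 0.83 to 0.93.

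Camera calls these 15 lists, 10 higher and 5 lower, with adjusted p-values of 1.3e-09 for ribosomal proteins, 2.2e-08 for heat shock, 1.6e-07 for arginine, 1.2e-06 for beta-oxidation, 4.8e-05 for iron uptake, 0.00013 for the other 4 amino acid synthesis lists, and 0.0029 to 0.036 for the remaining 6. All are lost with an estimated correlation: the adjusted p = 0.62 with an estimated correlation, and 0.66 for ribosomal proteins, and fry calls none (lowest adjusted p 0.35). The LAB libraries carry much of this. Without LAB replicate 2, lysine (0.13), histidine (0.57), aromatic synthesis (0.054), heat shock (0.057), hexose transporters (0.83), iron uptake (0.52), the tricarboxylic acid cycle (0.11), the glutamate list (0.61) and meiosis (0.70) are no longer called, and without LAB replicate 1 ribosomal proteins (0.66), glycolysis (0.41) and thiamine genes (0.69) are not. Without WY15 replicate 1, thiamine genes (0.22), the tricarboxylic acid cycle (0.071), the glutamate list (0.078) and meiosis (0.071) are lost, as are the glutamate list (0.057) and meiosis (0.10) without WY7 replicate 2 and meiosis (0.052) without WY15 replicate 2. Other lists are gained, such as ribosome biogenesis (3.6e-07) and ergosterol synthesis (1.1e-05) without LAB replicate 2. Arginine, branched-chain synthesis and beta-oxidation stay called without any 1 library. The arginine list medians, relative to the mean of the 8 *MED15* libraries, are -0.06 and -0.44 in LAB, -0.06 and 0.10 in WY7, -0.02 and 0.00 in WY15, 0.28 and 0.32 in WY23, and -1.16 and -1.32 in the deletion.

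**Figure D3:**
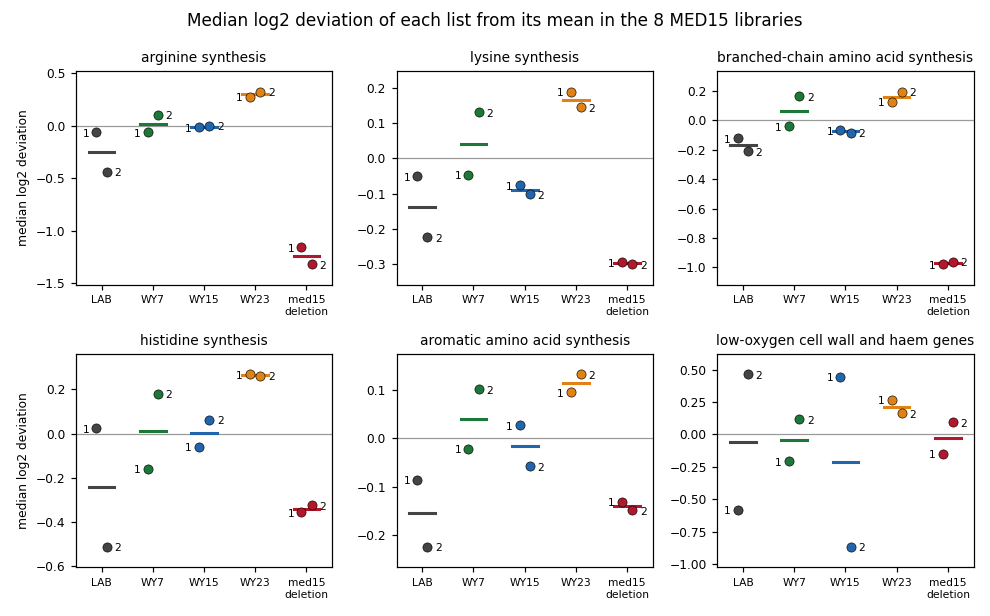
Median log2 deviation of the genes of 6 lists from their mean in the 8 *MED15* libraries (vertical axis) for each strain (horizontal axis); numbered points are replicates and bars their mean. Arginine medians are -0.06 and -0.44 in LAB, 0.28 and 0.32 in WY23 and -1.16 and -1.32 in the deletion; for the low-oxygen genes LAB replicate 1 and WY15 replicate 2 lie lowest. In the deletion, the lysine, branched-chain, histidine and aromatic medians against LAB turn positive under quantile normalization, and the arginine median is -0.04.

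WY23 has the most calls against LAB. Its arginine genes are higher in 10 of 10 cases (median 0.58), as are its 20 thiamine and vitamin B6 genes (median 0.38) and 22 of 23 ergosterol genes (0.24). The 20 thiamine and vitamin B6 genes include near-identical copies, so they are fewer separate measures. Ergosterol genes also differ within LAB, lower in replicate 1 than in replicate 2 by a median of -0.41. Lysine (9 of 9, 0.30), histidine (7 of 7, 0.51), branched-chain (10 of 11, 0.30) and aromatic synthesis (10 of 12, 0.28) lie higher too, and *HIS4* is at 0.62 (SE 0.22). Histidine genes differ within LAB too (0.02 and -0.51 relative to the mean of the 8 *MED15* libraries), and without LAB replicate 2 their median is 0.25, that of arginine genes 0.37. Camera calls 18 lists, 13 higher and 5 lower, with adjusted p = 4e-08 for arginine and for thiamine; all are lost with an estimated correlation (adjusted p = 0.60 to 0.64 with an estimated correlation). 6 of the 18 stay called without any 1 of the 8 *MED15* libraries: arginine, lysine, branched-chain and aromatic synthesis, thiamine genes and, lower, beta-oxidation. Among the other 12, histidine (0.059) and heat shock (0.059) are lost without LAB replicate 2, and ergosterol genes (0.69), ribosomal proteins (0.56) and ribosome biogenesis (0.97) without LAB replicate 1. By limma and by edgeR 0 genes pass, against 560 and 565 at an unadjusted p under 0.05 (303 by chance among 6065). DESeq2 calls 61 genes, 53 higher and 8 lower. Of the 97 genes tested in the amino acid lists 17 are among them, all higher. Chosen after their values were seen, these include *LYS20* (0.74, adjusted p = 0.0021), *ARG56* (0.57, 0.0021), *ILV2* (0.46, 0.0021), *ARG3* (0.95, 0.0082), and outside the lists the drug pump gene *SNQ2* (0.60, 5.6e-09) and *MCH5*, a riboflavin transporter gene (1.37, 1.3e-05). Among the 8 lower genes are *NDE1*, a mitochondrial NADH dehydrogenase gene (-1.25), and *HAP4*, an activator of respiration genes (-0.89).

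WY7 and WY15 have fewer list calls against LAB. In WY7, camera calls 14 lists, 13 higher (arginine 10 of 10 genes, median 0.23, adjusted p = 0.0012; heat shock 21 of 22, 0.34, 1.2e-08) and beta-oxidation lower. In WY15 it calls 10, 5 higher (arginine 10 of 10, 0.20, adjusted p = 0.0023) and 5 lower (hexose transporters 4 of 16 above LAB, -0.44, 0.0026; amino acid permeases 6 of 19, -0.25, 0.0023). All are lost with an estimated correlation, with lowest adjusted p-values of 0.82 for WY7 and 0.75 for WY15 with an estimated correlation. Camera calls 5 lists for WY7 without LAB replicate 2 and 7 without WY7 replicate 2, and 6 lists for WY15 without LAB replicate 2, where arginine is called for neither (0.61 and 0.68, medians 0.03 and -0.002). The permease median of WY15 is 0.04 without WY15 replicate 2 (0.60) and -0.03 without LAB replicate 2 (0.16), and that of the hexose transporters is -0.22 without LAB replicate 2 (0.44). The heat shock median of WY7 is 0.16 without LAB replicate 2 (0.044). Of the 14 WY7 lists only heat shock stays called without any 1 of the 8 *MED15* libraries, and of the 10 WY15 lists none. 6 lists are called in the same direction for all 3 alleles: arginine, histidine and aromatic synthesis, heat shock and ribosomal proteins higher, and beta-oxidation lower. The 3 comparisons share the LAB libraries, so such overlap is partly built in. Without LAB replicate 1 the ribosomal protein median is below 0 for each allele (-0.05, -0.03 and -0.07 for WY7, WY15 and WY23), and without WY15 replicate 1 the list is called lower in WY15 (-0.17, adjusted p = 5.8e-06). Of genes, limma and edgeR call 0 in either, with 285 and 276 at an unadjusted p under 0.05 for WY7 and 350 and 366 for WY15. DESeq2 calls 17 for WY7, 16 of them higher, and 4 for WY15, named after their values were seen: *MCH5* (1.09), *ANY1* (0.45), *CUP2* (-0.49) and *DPI8* (-0.78). For the mean of the 3 alleles limma and edgeR call 0 (300 and 324 at an unadjusted p under 0.05) and DESeq2 calls 5: *MCH5* (1.00), *YOR203W* (0.63), *LYS20* (0.58), *SNQ2* (0.47) and *USB1* (-0.52), also named afterwards. Simulated 2-fold changes were called in 86.5% of genes for 1 allele and in 91.5% for the mean of 3, and 1.5-fold changes in 7% and 52%, so differences of 1.5-fold in a single allele were mostly not detectable with 2 libraries. The simulated changes lay in genes with a mean of at least 50.

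All 20 thiamine and vitamin B6 genes are lower in WY7 (median log2 -0.31) and in WY15 (-0.39) than in WY23. Several of the 20 have near-identical copies, *THI5* and *SNZ2* among them, so they are not 20 separate measures. The WY15 libraries differ in this list (0.09 and -0.33), and the WY15 median is -0.14 without WY15 replicate 2 and -0.57 without replicate 1, called in both cases. General stress genes are higher in WY7 than in WY15 (median 0.40) and WY23 (0.39), as are trehalose and glycogen genes (0.35 and 0.40). The WY15 libraries differ from each other in both lists, lower in replicate 1 than in replicate 2 by -0.33 and -0.84, and for trehalose and glycogen WY15 replicate 2 (0.23) lies between the WY7 libraries (0.39 and 0.12). Without WY15 replicate 1 neither list is called between WY7 and WY15 (0.40 and 0.96, medians 0.09 and 0.04). Camera calls 6 lists between WY7 and WY15, 12 between WY7 and WY23 and 10 between WY15 and WY23 (12 between WY7 and WY15 without WY15 replicate 2), and none with an estimated correlation (adjusted p = 0.68 to 0.92 with an estimated correlation). No gene passed by limma or edgeR in any of the 3, with 711, 320 and 408 at an unadjusted p under 0.05 by limma and 709, 327 and 401 by edgeR, against 157, 11 and 48 calls by DESeq2. The test for any difference among the 4 alleles gives 0 by limma and edgeR (491 and 483 at an unadjusted p under 0.05) and 155 by DESeq2. Without LAB replicate 1 and WY15 replicate 2, left out together only after seeing the data, limma calls 309 genes between WY7 and WY15, 143 higher and 166 lower in WY7, where the full set calls 0 and the lowest adjusted p is 0.14.

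Across genes, the changes of WY7 and of the deletion are negatively correlated. Over 6065 genes, which are not independent replicates, the covariance of the deletion and allele changes against LAB is -0.041 for WY7, 0.029 for WY15 and 0.015 for WY23, where unchanged strains compared with the same LAB libraries gave 0.022 in 1000 simulations. With no library shared between the 2 changes it is -0.062 for WY7, 6.5e-06 for WY15 and -0.022 for WY23, so the sign for WY23 depends on the shared libraries (correlations across genes -0.37, 3.1e-05 and -0.09). The simulated genes varied independently and 0.022 is only the mean of the simulations. How far unchanged strains would stray from it was not measured. Camera with the preset correlation calls 7 lists both for the deletion and for the mean of the WY alleles. Of these 5 lie in opposite directions. Glycolysis, arginine and branched-chain synthesis are lower in the deletion (arginine and branched-chain genes with the scaling limits above), and beta-oxidation and meiosis are higher in it. None is called with an estimated correlation in either comparison (lowest adjusted p = 0.40 and 0.62 with an estimated correlation), and the LAB libraries are shared.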

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

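Of the tests in this part, the list tests between WY alleles were chosen after the first results were seen, and the splits of the libraries were planned before. Each of the 3 results below is here because 2 alleles differed from each other in a direct test of that difference.

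Between WY7 and WY15, 6 lists differed by camera with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.81), 5 higher and 1 lower in WY7: general stress, trehalose and glycogen, sulfate and methionine, the tricarboxylic acid cycle and the respiratory chain higher, and ribosome biogenesis lower. Each of the 6 is lost or turns when 1 library is left out. Without WY15 replicate 1, general stress (adjusted p = 0.40), trehalose and glycogen (0.96), the tricarboxylic acid cycle (0.22) and the respiratory chain (0.78) are no longer called, and ribosome biogenesis turns higher in WY7 (0.00036, median 0.16). Sulfate and methionine is lost without WY7 replicate 2 (0.14). Between WY7 and WY23, 12 lists differed (0 with an estimated correlation, lowest adjusted p = 0.68), 7 higher and 5 lower in WY7, with thiamine and vitamin B6 genes lower in 20 of 20 cases (adjusted p = 1.9e-10) and respiratory chain genes higher in 31 of 33; 6 of the 12 stay called without any 1 of the 8 *MED15* libraries, these 2 lists included. Between WY15 and WY23, 10 lists differed (0 with an estimated correlation, lowest adjusted p = 0.87), 1 higher and 9 lower in WY15, among them thiamine genes (adjusted p = 5.5e-09), arginine and ergosterol synthesis; 3 of the 10 stay called without any 1 library (thiamine, arginine and lysine), and ergosterol is lost without WY15 replicate 2 (0.86). fry calls 0 lists in any of the 3. The 20 thiamine and vitamin B6 genes include near-identical copies that share reads, which the preset correlation does not allow for.

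The preset correlation gives many calls between strains in which no gene passes by limma. For the 15 lists called between the mean of the WY alleles and LAB, 5 of the 28 choices of 2 of the 8 *MED15* libraries gave as many lists, the real one included, and the highest other choice gave 20, so chance is not excluded for that count. 2 choices gave 20 lists, 1 of which is the WY23 pair and the other LAB replicate 2 with WY15 replicate 2. For the deletion, taken as 2 libraries against the other 8, 1 of 45 choices gave as many genes, the real one, with 3047 genes. The highest other gave 11 (LAB replicate 2 with WY7 replicate 1). Every other choice leaves a deletion library among the other 8, which widens the spread there. These splits therefore cannot tell how many genes chance would call.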

How the results depend on the processing

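The alternatives that leave out 2 libraries together or *URA3* from the marker list, and the list tests between WY alleles, are tests chosen after the data were seen; the others were planned. Against the values given, 355 of 393 counts under an alternative stayed within 1.5 times, 5509 of 5824 gene tests and 1092 of 1226 list tests kept their side of the threshold, and their direction where called, 178 gene tests and 82 list tests lost a call, 127 and 49 gained one, and 10 and 3 changed direction with a call before or after. Leaving out 1 library at a time gave 1480 to 2500 genes for the deletion against LAB and 2075 to 3279 against the mean of 4; the lone library left in a group is then assumed to vary like the other groups. The replicate block gives 2051 and 2888 for these and 0 for the comparisons among alleles. The fit with only the groups compared gives 1639 against LAB and, by construction, no change against the mean of 4. Robust weights, pseudocounts and filters kept both deletion counts within 1.5 times.

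DESeq2 on recovered reads calls 17 (WY7), 4 (WY15), 61 (WY23), 5 (mean), 157 (WY7 versus WY15), 11 (WY7 versus WY23), 48 (WY15 versus WY23) and 155 genes (any difference), where limma and edgeR call 0; the cause was not tested. Leaving out single libraries gives 0 to 1 genes for WY7 versus WY15. Without LAB replicate 1 and WY15 replicate 2 together, limma calls 2 genes for WY15 versus LAB, 309 for WY7 versus WY15, 1 for WY15 versus WY23 and 2 for any difference, and 12 lists for WY7 versus WY15. Without LAB replicate 2 and WY7 replicate 1, it calls 1413 genes for the deletion against LAB, 1341 of them shared with the full set, and 8 lists for WY7 versus LAB. Both remove replicates; the cause was not tested further.

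An estimated correlation leaves 0 lists in all 9 comparisons. It rests on few residual degrees of freedom and its power was not measured, so these losses do not show that no list moved. fry gives 27 lists for the deletion against the mean of 4 and 0 for the 7 comparisons among alleles. Leaving out single libraries gives 5 to 16 lists for WY7 versus LAB (5 without LAB replicate 2, 7 without WY7 replicate 2), 6 to 14 for WY15 versus LAB (6 without LAB replicate 2) and 6 to 12 for WY7 versus WY15 (12 without WY15 replicate 2).

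Among the genes open to naming, 9 that are called on either scale turn from negative to positive in the deletion under quantile normalization (sign changes without a call on either are not counted): *BAT1* 0.81, *ARO8* 0.57, *CPA1* 0.0024, *ARG7* 0.91, *LEU1* 0.20 (0.205), *ILV3* 0.56, *TRP5* 0.75, *HOM2* 0.44 and *ACO1* 0.48, as does *THI3* (0.32) under equal sums. Quantile normalization forces 1 distribution on libraries whose 100 top genes hold 12.7 to 28.2% of the reads. fry calls the selection markers higher (adjusted p = 1.3e-06), where camera's direction is lower. *URA3* carries this: without it fry calls the list lower (0.0015), as does camera (0.037; 0.61 with an estimated correlation). The nitrogen catabolite repressed list is not called for the mean of the WY alleles (adjusted p = 0.89), is called higher without LAB replicate 1 (0.019) and lower without LAB replicate 2 (0.016; 0.016 to 0.94 over single libraries left out) and without LAB replicate 2 and WY7 replicate 1 (0.035). With no shared library the covariance of deletion and allele effects is -0.062 for WY7, 6.5e-06 for WY15 and -0.022 for WY23, the last with a changed sign. The replicate spread exceeds counting error in all 5 strains (chi-square per degree of freedom 21.7 to 181), and all alternatives listed beforehand were run.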

Other observations

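The lists not described above are not called by camera in the deletion against LAB. Their counts stand beside 2219 called genes among all 6065, so single called members do not show that a list moved. Iron uptake genes had 7 of 18 higher and 0 lower by both counts (over all genes and adjusted over the list alone), with the siderophore transporter gene *SIT1* at 1.87 and the reductase genes *FRE2* at 1.55 and *FRE1* at 1.47; the list is called against the mean of 4 (adjusted p = 0.013, and adjusted p = 0.64 with an estimated correlation) but not against LAB (0.082), where it passes without LAB replicate 2 (0.010) or deletion replicate 2 (0.013). Mating genes had 9 of 20 higher and 2 lower by both counts (adjusted p = 0.14; 0.034 without deletion replicate 2), with *HO*, the mating-type endonuclease gene, at 1.76 and *FIG1* at 1.22 beside the fall of *MF(ALPHA)1*; quantile normalization gives 6 higher and 3 lower, equal sums 13 and 1. Of 25 Mediator genes 5 rose and 5 fell by both counts, with *MED2*, another tail subunit, at -1.01 (SE 0.18, adjusted p = 0.0032) and the kinase module subunit *SSN2* at 0.54, and camera gives 0.36. That even split belongs to the deposited scale and TMM: 2 are higher and 6 lower under quantile normalization, and 13 and 2 under equal sums, where the list median (-0.07) turns positive. *MED15*, the deleted gene, is itself a Mediator subunit and adds to the lower side. The list was not tested without it, so the fry call of this list as lower (adjusted p = 1.1e-05) may rest on that gene. Heat shock chaperones had 3 of 22 higher and 1 lower by both counts, with *SSA3* at 1.48 and *HSP26* at -1.84, the latter not called under quantile normalization. There 8 are higher and 0 lower (median 0.40, against 0.09), and under equal sums 8 and 1.

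Low-oxygen genes had 5 of 18 higher and 1 lower by both counts (*AAC3* at 2.19; adjusted p = 0.56). Fusel alcohol and ester genes had 5 of 12 lower and 0 higher (5 and 1 adjusted over the list alone; 0.24), with *EEB1*, an ester synthesis gene, at -1.57; inositol and phospholipid genes had 5 of 17 lower and 1 higher by both counts (0.30), with *ITR1*, an inositol transporter gene, at -1.36; and drug resistance genes had 4 of 12 lower and 1 higher (4 and 2 adjusted over the list alone; 0.41), with *RSB1* at -2.11. The medians of these 3 lists change sign under equal sums or quantile normalization, where the counts of higher and lower genes are 3 and 3 (fusel), 1 and 5 (inositol) and 2 and 4 (drug resistance), and under equal sums 4 and 1, 5 and 3, and 4 and 4. The tricarboxylic acid cycle had 3 of 18 higher and 4 lower by both counts (0.82), a balance that turns to 10 higher and 2 lower under quantile normalization (median 0.38, against 0.05) and to 9 and 2 under equal sums. Phosphate genes had 4 of 16 higher and 3 lower by both counts (0.62; 2 higher and 4 lower under quantile normalization), and galactose genes 2 of 8 higher and 1 lower (3 and 1 adjusted over the list alone; 0.20). Ergosterol genes had 2 of 23 higher and 1 lower (1 and 1 adjusted over the list alone; 0.91), and ribosome biogenesis 1 of 61 higher and 4 lower (0 and 0 adjusted over the list alone; 0.20, but 0.017 without LAB replicate 1). Under equal sums phosphate genes have 8 higher and 1 lower, galactose genes 6 and 1, ergosterol genes 9 and 1 (median 0.40, against 0.04) and ribosome biogenesis 13 and 1, with a median that turns positive. The selection markers had 1 of 6 higher, *URA3* (11.65), and 4 lower (2 and 4 adjusted over the list alone; 0.33), with the arginine permease gene *CAN1* at -1.84. Median, mean and test differ in sign for the ergosterol, tricarboxylic acid and marker lists.

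The tests on *URA3*, and those of depth and oxygen for the low-oxygen genes, were chosen after those results were seen; the test of the fermentation point and those of the allele order were planned before. *URA3* reads appear in the deletion libraries alone, with 3971 in the lower of them and 0 in every other library. Induction of the pyrimidine pathway is argued against, since the other 8 genes have a median log2 change of 0.1185 (SD 0.70). A candidate explanation is a *URA3* gene present only in the deletion strain, such as a marker at the deleted locus, and the reads fit that. Uracil prototrophy may lie behind part of the other changes; 2 of the 8 pyrimidine genes changed (*URA8* 1.20, *URA2* -1.17), and it cannot be told apart from the loss of *MED15*, because no library has one without the other.

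Low-oxygen genes were low in LAB replicate 1 and WY15 replicate 2. Depth is argued against, as these hold 0.980 and 0.8848 times the reads of their partners while the list differs by -1.05 and -1.41. A difference in oxygen between the tubes is a candidate explanation: ergosterol genes, a separate list, are lower in 22 of 23 cases in both (medians -0.4058 and -0.52), although the labels give no oxygen value. A different point of the fermentation or growth state cannot be told apart: hexose transporters differ by -0.6208 in LAB but by -0.03 in WY15, and glycolysis by -0.14 and -0.30. In LAB and WY15, ribosomal proteins differ between replicates 1 and 2 by -0.45 and 0.74 and ribosome biogenesis by -0.24 and 0.54, both lower in the low-oxygen-poor library, and trehalose and glycogen by 0.01 and -0.84; no group of the design separates these libraries.

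On an axis from the mean of the 8 *MED15* libraries (0) to the deletion (1), the strains score 0.033 (SD 0.0067, LAB), 0.031 (SD 0.0028, WY15), -0.0046 (SD 0.0039, WY23) and -0.059 (SD 0.023, WY7), so WY7 lies farthest from the deletion. Of 105 ways to pair the 8 libraries, 3 gave a spread within pairs as small, the real one included (real 0.000584). The smallest other spread, 0.000546, lies below the real one, so chance is not excluded for that closeness. The scores go with reads (Pearson r = 0.854, exact permutation p = 0.0058, and Spearman rho = 0.667, exact permutation p = 0.083, two-sided, 1 relation computed). Without the 2 libraries farthest in depth, both WY7, r = 0.563, so the relation rests on them. The permutations treat the 8 libraries as independent, although they are 2 from each of 4 strains, so both p-values may be too small. Leaving out the 500 most abundant genes kept 0.9446 of the difference between WY7 and LAB, which argues against a few abundant genes. Thinning all libraries to 22.7 M reads kept 0.9907 of the difference and moved no score by more than 0.0012. That argues against the number of reads sampled as its source. Both WY7 libraries hold the fewest reads, so anything else that goes with the reads of a library cannot be told apart from an allele effect.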
